A study of Danio rerio with 2 samples.

How the data were processed

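Cells positive for a gata1-EGFP transgene were sorted from *add1* knockout embryos and their siblings at 22 hours post fertilization, per the labels. RNA was prepared with the SMART-Seq HT kit, which amplifies full-length cDNA by PCR and adds no molecular identifiers, and sequenced on a BGISEQ-500, per the labels' protocols. Reads were mapped to the zebrafish genome, build GRCz10 per the submitters' processing notes. The aligner, the counter, the strand setting and any filters are not given in the sources used here. The deposited table held 32105 genes with their positions, and coordinates are those of the table. For each library the authors deposited raw read counts per gene and FPKM (fragments per kilobase of gene, scaled to library size). FPKM per count differed between the libraries by a factor of 1.03, from 1.0329 to 1.034 over genes with a count in both, against a ratio of count totals of 1.0338, so the deposited FPKM follow the totals of the table.

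The labels gave 2 groups, the add1 mutant and the wild-type sibling, with 1 library in each. No test across samples and no p-value was possible, and the comparison is between these 2 libraries. Counts were divided by library totals multiplied by TMM factors (edgeR 4.0.16 in R 4.3.3, used for scaling factors only), 1.07 for the mutant and 0.9345 for the sibling library, to give CPM. Log2 ratios are of CPM + 1, mutant over sibling, and a gene was measured if it reached 10 CPM in the higher library, which is 63.7 counts in the mutant and 57.5 in the sibling library. Genes were counted as higher or lower if this ratio was at least 2-fold. Folds in the text are ratios of CPM without the added 1, with exact (Clopper-Pearson) 95% intervals for counts. For a gene with 0 counts in a library, the fold is a bound set by a floor of 3 counts, or 0.471 CPM in the mutant and 0.521 CPM in the sibling library. This bound leaves out the counting error of the other library. Shares of counts have exact binomial intervals.

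The design, 32 gene lists (1189 symbols) and the alternatives were fixed before the data were examined. Of the symbols, 1066 were found as gene names in the table and 48 more through gene IDs, and 26269 gene IDs of the table were in the name table used. For each list with at least 5 measured genes (30 lists, without 1 list that is not reported here) the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and a list stood apart below percentile 2.5 or above 97.5. The list of replication-dependent histone genes had 1 measured gene, *hist2h2l* (63.1 against 23.8 CPM), and was not tested. The proteasome list took in *psmc3ip*, which is not a subunit, by its name pattern. Setting the single members with 0 sibling counts in the neural and interferon lists at their bounds left the medians at 0.89 and 0.35.

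The genes named are *add1*, the 12 with the highest and the 12 with the lowest ratio among genes with a symbol that is not a clone or zgc identifier and at least 20 CPM in the higher library, up to 4 measured members of each list with the largest absolute ratio, and in every case *gata1a*, *alas2*, *slc4a1a* and the 3 most abundant globins. Other genes, among them *klf1*, *lmo2*, *gfi1b* and *myb*, and *he1a* and *hmgcrb*, which are labelled in figures only, and the sums over gene families, were chosen after their values were seen. So was the stretch at the start of chromosome 21, for which the median over windows of 10 neighbouring measured genes was computed along every chromosome.

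Alternatives were CPM by library total, median-of-ratios and upper quartile scaling, totals without globin, mitochondrial and ribosomal protein genes, pseudocounts of 0.1 and 5, minimums of 1 and 50 CPM, no minimum, a minimum in both libraries, rules of 1.5-fold and 4-fold, FPKM, counting intervals that exclude 1, 10 expression bins, and lists without shared members. Counts without the stretch on chromosome 21, counts without the muscle, neural, epidermis, yolk and hatching gland marker lists, and a scaling to the erythroid factor list were added after seeing the data. Median log2 ratios by quartile of gene length, from the counts and FPKM, were -0.06, -0.04, -0.08 and -0.10.

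The rules were tested on simulated counts with the depths of these libraries. With no spread between samples, 100% of 4-fold and 34% of 2-fold changed genes passed the 2-fold rule, 0 of 9062 unchanged genes did, and 95.6% of the counting intervals of 9040 genes held the true ratio. With an assumed coefficient of variation of 0.2 between samples, 201 of 9191 unchanged genes passed, and with 0.4, 2240 of 9335 did. Since the spread between embryos is unknown here, the 1106 genes past 2-fold cannot be read as a count of regulated genes. Lists were simulated with no spread between samples and with genes drawn independently. Of 100 lists drawn at random from these genes, 2 fell outside the percentiles, and 100 of 100 lists raised by 0.5 on the log2 scale were found. Lists whose genes vary together were not simulated, so these rates need not hold for the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.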

Results

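The series measured RNA in gata1-EGFP-positive cells of zebrafish embryos at 22 hours post fertilization. The transgene marks cells that use the promoter of *gata1a*, the master transcription factor of red cell formation, and the labels call the sorted cells erythroblasts. There was 1 library from *add1* knockout embryos and 1 library from siblings labelled wild type, and the comparison asked what the loss of *add1* does to the transcriptome before a shortage of red cells can be seen. The mutant library held 5956344 counts over 20148 genes and the sibling library 6157792 counts over 19283 genes. With 1 library per genotype no difference has a replicate check and no test across embryos was possible, so genotype cannot be told apart from any difference between the preparations. Intervals given with folds are exact 95% counting intervals of the ratio of CPM, counts scaled to library size. They cover the counting of reads only, and no spread between embryos. The reads carry no molecular identifiers, so copies made by PCR were counted as separate reads and the intervals may be too narrow.

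*add1*, which encodes adducin 1, a protein that caps actin filaments and joins them to spectrin, was nearly absent from the mutant library. The gene (ENSDARG00000103962, chromosome 21, 1964471 to 2042174, GRCz10) had 18 counts in the mutant library and 1166 in the sibling library. These corresponded to 2.82 and 203 CPM, a level 71.7-fold lower in the mutant library (45.2 to 121).

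The low level was not limited to *add1*. The 12 measured genes between the start of chromosome 21 and the end of *add1*, at base 2042174, were all at least 12.5-fold lower in the mutant library by their ratio of CPM. Together they had 276 counts in the mutant library and 14033 in the sibling library, a remaining level of 1.78% (1.57 to 2.0). Among them were *oaz1b*, an ornithine decarboxylase antizyme gene, at 14.4 against 877 CPM, and *jak2a*, the kinase that carries the erythropoietin signal, at 8.32 against 499 CPM. *fech*, which encodes ferrochelatase, the last enzyme of heme synthesis, was at 2.2 against 157 CPM. *nars*, *txnl1*, *bxdc2*, *zer1* and *wdr91* were also in this group, with folds of 57.9, 47.9, 44.5, 200 (35.5 to 7961) and 70. The value of *zer1* rested on 1 count in the mutant library and that of *wdr91* on 3 counts. Of the 27 genes of this stretch with more than 3 counts in all, 0 were higher in the mutant library. The next 12 measured genes, from 2066071 to 3462281, had a median log2 ratio of 0.29, with a range from -0.84 to 1.48. On the rest of the chromosome 4.65% of 344 measured genes were at least 2-fold lower, within the 2.55 to 5.90% of the other 24 chromosomes.

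**Figure D1:**
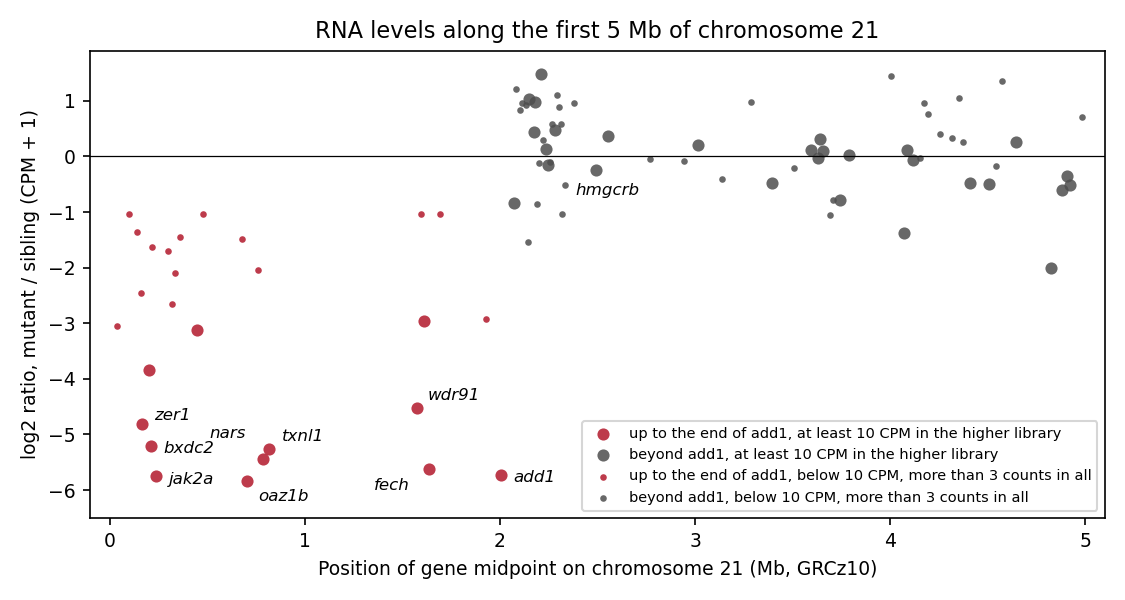
Log2 ratio of mutant to sibling CPM (each + 1) against gene position in Mb over the first 5 Mb of chromosome 21, 1 point per gene, large where at least 10 CPM was reached in the higher library. The 12 large red points up to the end of add1 lie far below 0, and the next 12 measured genes have a median of 0.29.

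Over the genome, 9625 genes reached 10 CPM in at least 1 library. Of these, 685 were at least 2-fold higher and 421 at least 2-fold lower in the mutant library, 142 and 41 of them at least 4-fold. Outside the first part of chromosome 21, the named genes with the lowest ratios were *E2F2*, a cell cycle transcription factor (8.47 against 78.2 CPM), *ampd2a*, an AMP deaminase (87.4 against 564 CPM), and *rfesd* (13.3 against 87.1 CPM). *cpa5*, a mast cell carboxypeptidase with 3 mutant counts, was at 0.471 against 13.2 CPM, below the level required for naming by size. At the other end stood *phlda3*, *sox11b*, *hsp70.1*, *cmn*, *lnx1*, *cpn1* (ENSDARG00000096720), *he1b*, *atxn1b*, *isg15*, *RNF14 (1 of many)* (ENSDARG00000078683), *ctslb* and *mmp2*. *phlda3* was at 129 against 1.91 CPM, 67.6-fold higher (37.6 to 136). *lnx1*, a ubiquitin ligase gene, was at 198 against 6.78 CPM, *atxn1b* at 223 against 8.51 CPM, and *mmp2*, a matrix metalloproteinase, at 197 against 10.1 CPM. *sox11b* had 256 counts against 0 and was 77.1-fold higher against the floor of 3 counts, with a lower limit of 62.2. *isg15* had 128 counts against 0 and was 38.5-fold higher against the same floor, with a lower limit of 30.9. Other scalings moved the split between higher and lower genes: 981 and 248 with CPM by library total, 845 and 309 with totals that left out globin, mitochondrial and ribosomal protein genes, and 434 and 150 with FPKM, where the scaling and the genes that passed the minimum (5999 in place of 9625) both changed. The median log2 ratio of measured genes was -0.07, and 0.12 with CPM by library total.

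**Figure D2:**
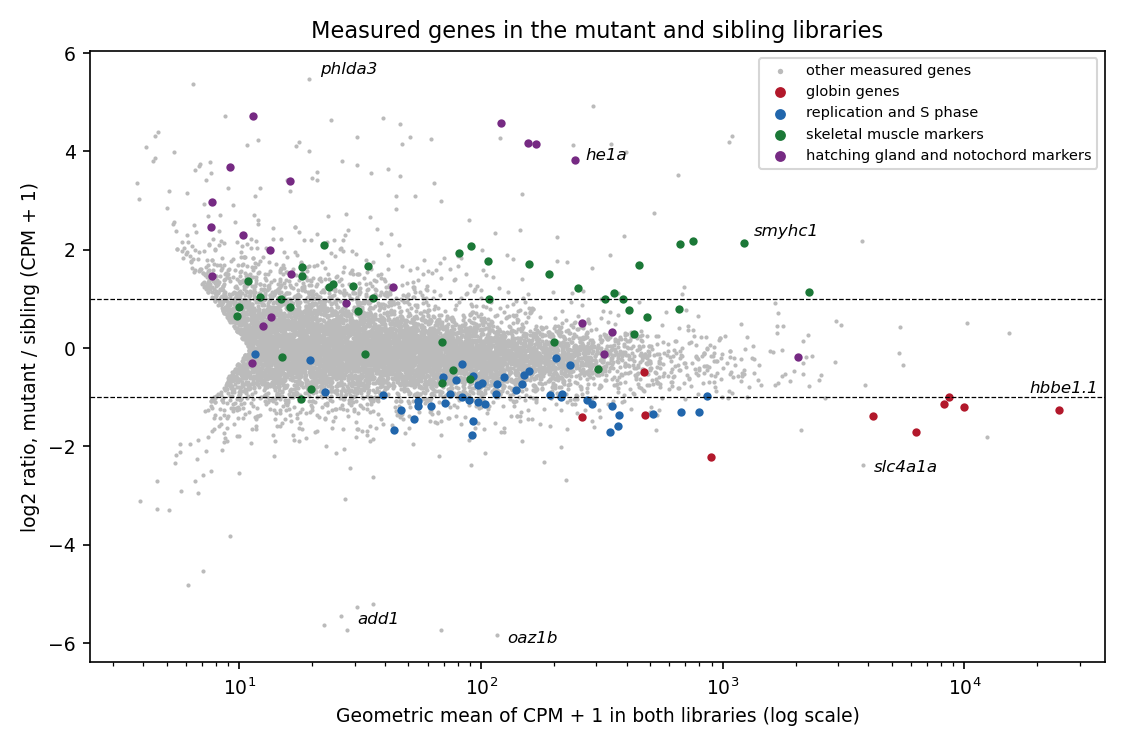
Log2 ratio of mutant to sibling CPM (each + 1) against the geometric mean level of both libraries on a log axis, 1 point per measured gene (9625 genes), with dashed lines at the 2-fold rule. Globin genes and S phase genes lie mostly below 0, and skeletal muscle and hatching gland and notochord markers mostly above it.

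The genes of the globin list made up 4.44% (4.43 to 4.46) of counts in the mutant library and 9.27% (9.25 to 9.29) in the sibling library. All 10 measured globin genes were lower in the mutant library, 8 of them at least 2-fold, with a median log2 ratio of -1.31 (percentile 0.0 among random lists matched on expression). *hbbe1.1* was at 15890 against 37884 CPM, *si:ch211-5k11.2* (ENSDARG00000088330) at 6603 against 15101 CPM and *hbae3* at 6115 against 12117 CPM. *hbae1* was at 414 against 1928 CPM. The spans of *hbbe1.1*, this *si:ch211-5k11.2* and *hbae1* overlap on chromosome 3, so how reads were divided among them is uncertain. The summed level of the list was 2.39-fold lower (2.38 to 2.40), and 2.54-fold lower (2.53 to 2.55) with *si:ch211-5k11.12*, which lies within the span of *hbbe1.1* and is not in the list. *slc4a1a*, the band 3 anion exchanger of the red cell membrane, was 5.24-fold lower (5.13 to 5.35), at 1665 against 8723 CPM. *cahz*, the red cell carbonic anhydrase, was 3.19-fold lower (3.11 to 3.28).

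The other lists of red cell products were lower by less. The heme synthesis and iron uptake list had a median of -0.45 (percentile 0.05), with 4 of 39 genes at least 2-fold lower and 0 higher. The 4 were *fech*, which lies in the stretch of chromosome 21, the transferrin receptor gene *tfr1a* (207 against 624 CPM), *ppox* (241 against 511 CPM) and *alas2*, the erythroid first enzyme of heme synthesis (1865 against 3785 CPM). The erythroid enzyme and antioxidant list had a median of -0.50 (percentile 0.07), with 3 of 23 genes at least 2-fold lower, *cahz*, *tspo* and *creg1*, and 1 higher, *bpgm*. The membrane skeleton list had a median of -0.50 (percentile 0.15) over 22 genes. Its 2 lower members were *slc4a1a* and *tmod4*, a tropomodulin, and its 2 higher members *ank1a* and *TPM1*. With a minimum of 1 CPM the median of this list was 0.02, so its direction depended on the minimum.

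Erythroid transcription factors and signalling genes did not stand apart as a list, with a median of -0.13 (percentile 63.9), 5 of 31 genes at least 2-fold lower and 1 higher. *gata1a* itself was 1.53-fold lower (1.47 to 1.60), at 582 against 892 CPM. *jak2a*, of the stretch on chromosome 21, *E2F2* and *foxo3a* (25.6 against 86.5 CPM) were among the lower members, and *foxo3b*, its paralog, was the higher one (451 against 92.6 CPM). The hematopoietic progenitor list, which shares 5 of 13 members with other lists, had a median of 0.03 (percentile 86.7), with *hlfa* at 9.10 against 21.7 CPM and *mycn* at 86.5 against 57.7 CPM. Beside these erythroid lists, markers of skeletal muscle were higher in the mutant library, with a median of 1.01, and those of endothelium were not, with a median of 0.02.

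Genes of DNA replication and S phase were lower in the mutant library in 46 of 46 cases, 21 of them at least 2-fold, with a median of -0.98 (percentile 0.0). *ccne2*, a cyclin of the G1 to S transition, was at 48.8 against 168 CPM. *mcm5* and *mcm3*, subunits of the replicative helicase, were at 189 against 617 CPM and 212 against 636 CPM. *pola1*, a DNA polymerase subunit, was at 23.5 against 77.0 CPM. The mitosis list had a median of -0.75 (percentile 0.0), with 52 of 53 genes lower and 8 at least 2-fold, among them *cdc25b* (171 against 480 CPM), *kpna2* (190 against 504 CPM), *top2a* (137 against 331 CPM) and *kif11* (225 against 495 CPM). Chromatin remodelling and modifying factors had a median of -0.34 (percentile 0.0), with 74 of 101 genes lower. The maintenance DNA methyltransferase gene *dnmt1* (68.3 against 163 CPM), the cohesin subunit gene *stag1b* (65.0 against 151 CPM) and the insulator protein gene *ctcf* (51.5 against 119 CPM) were the 3 that passed 2-fold. The library with these lower values also had higher markers of skeletal muscle and of hatching gland and notochord, with medians of 1.01 and 1.75.

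Cytosolic ribosomal protein genes were lower in 75 of 78 cases, with a median of -0.50 (percentile 0.0), and 2 of them, *rpl39* and *rps9*, passed 2-fold. The other 3 were *rpl35a* and 1 of 2 genes named *rpl37* (ENSDARG00000076360, 47.5 against 41.9 CPM), neither of them past 2-fold, and the *rps27.2* on the unplaced sequence KN150108.1, which was 6.76-fold higher (6.36 to 7.20), at 1344 against 199 CPM. The name table gives this copy as *rps27l*. Without the 2 genes named *rps27.2* the summed level of the list was 1.43-fold lower (1.42 to 1.44). The 13 mitochondrially encoded genes were all lower, none by 2-fold, with a median of -0.52 (percentile 0.80), but with a minimum of 50 CPM this list no longer stood apart (-0.48, percentile 10.5). Nuclear oxidative phosphorylation genes had a median of -0.21 (percentile 9.78) and proteasome genes one of -0.14 (percentile 74.4), and neither list stood apart. In the same library markers of skeletal muscle and of hatching gland and notochord were higher, with medians of 1.01 and 1.75.

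Apoptosis regulators did not stand apart as a list, with a median of 0.05 (percentile 89.7), and 2 of 23 genes were at least 2-fold higher. With a minimum of 50 CPM the list did stand apart, with a median of 0.28. *bbc3*, which encodes the pro-apoptotic protein Puma, was 14.8-fold higher (10.9 to 20.7), at 111 against 7.47 CPM. *casp8*, an initiator caspase gene, was 6.72-fold higher (5.27 to 8.69), at 86.5 against 12.9 CPM. Skeletal muscle markers, of cells outside the erythroid lineage, with a median of 1.01, were higher in the same library.

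Stress lists were mixed. Immediate early genes had a median of 0.22 (percentile 99.98), with 3 of 38 at least 2-fold higher (*ctgfa*, which is also in the hatching gland and notochord list, *myca* and *fosab*) and 1 lower (*klf2b*, 62.3 against 143 CPM). *fosab* (ENSDARG00000097234, of 2 genes of that name) was at 539 against 249 CPM. Markers of skeletal muscle and of hatching gland and notochord, with medians of 1.01 and 1.75, were higher in the same library. Heat shock and chaperone genes had a median of -0.05 (percentile 95.6) with 4 of 33 at least 2-fold higher, *hsp70.1*, *serpinh1b*, *hspb1* and *bag3*, and stood apart only with a minimum of 50 CPM (0.01). *hsp70.1* was at 1599 against 51.6 CPM, and over *hsp70.1*, *hsp70.2*, *hsp70.3* and *hsp70l* together the level was 1.53-fold higher (1.52 to 1.55). Reads shared among these genes could not be traced. The unfolded protein and integrated stress response list had a median of -0.13 (percentile 55.5), with *atf5a* at 257 against 49.7 CPM and *shmt2* at 160 against 336 CPM. Nrf2 targets (-0.21, percentile 28.8), glycolysis and hypoxia genes (-0.08, percentile 70.8), autophagy genes (0.01, percentile 84.1), actin regulators (-0.10, percentile 74.7) and interferon genes (0.35 over 6 genes, percentile 89.6) did not stand apart.

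Markers of other cell types differed between the libraries in both directions. Hatching gland and notochord markers had a median of 1.75 (percentile 100), with 14 of 22 at least 2-fold higher, and 6 of the 22 in other lists too. *he1b*, a hatching enzyme, was at 592 against 23.6 CPM, and the notochord gene *cmn* at 57.3 against 1.22 CPM. Skeletal muscle markers had a median of 1.01 (percentile 100), with 23 of 44 at least 2-fold higher and 1 lower. *smyhc1*, slow myosin heavy chain, was at 2568 against 579 CPM, and *myl13* and *myl10*, myosin light chains, at 1605 against 351 CPM and 1387 against 317 CPM. Neural markers had a median of 0.89 (percentile 100, 11 of 33 higher by 2-fold, 1 lower), with *isl1* at 39.2 against 6.78 CPM and *stmn1b* at 86.8 against 28.3 CPM. Epidermis and periderm markers had a median of 0.38 (percentile 100) with *agr1* at 26.2 against 7.47 CPM. Yolk and plasma protein genes had a median of 0.86 over 7 genes (percentile 99.6), but 2 of those with high ratios were copies of *ctslb*, and with a minimum of 1 CPM the list no longer stood apart (0.18, percentile 70). Myeloid markers were lower, with a median of -0.38 (percentile 0.15), 10 of 37 at least 2-fold lower and 1, *mmp13a*, higher. With a minimum of 50 CPM they no longer stood apart (-0.30, percentile 11.7). Of the 37 genes, 27 were lower at all and 10 higher, among these *spi1b* (107 against 71.8 CPM) and *cebpa* (250 against 163 CPM). *lyz*, lysozyme, was at 38.8 against 206 CPM, *il1b*, an inflammatory cytokine, at 11.3 against 65.9 CPM, and *npsn*, a neutrophil protease, at 3.14 against 16.3 CPM. Thrombocyte markers went both ways, with *itga2b* at 26.8 against 10.9 CPM and *gp9* at 27.5 against 74.2 CPM, and their median of 0.07 (6 genes, percentile 58.3) did not stand apart. Endothelial markers had a median of 0.02 (percentile 55.2), with 0 of 28 past 2-fold in either direction.

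**Figure D3:**
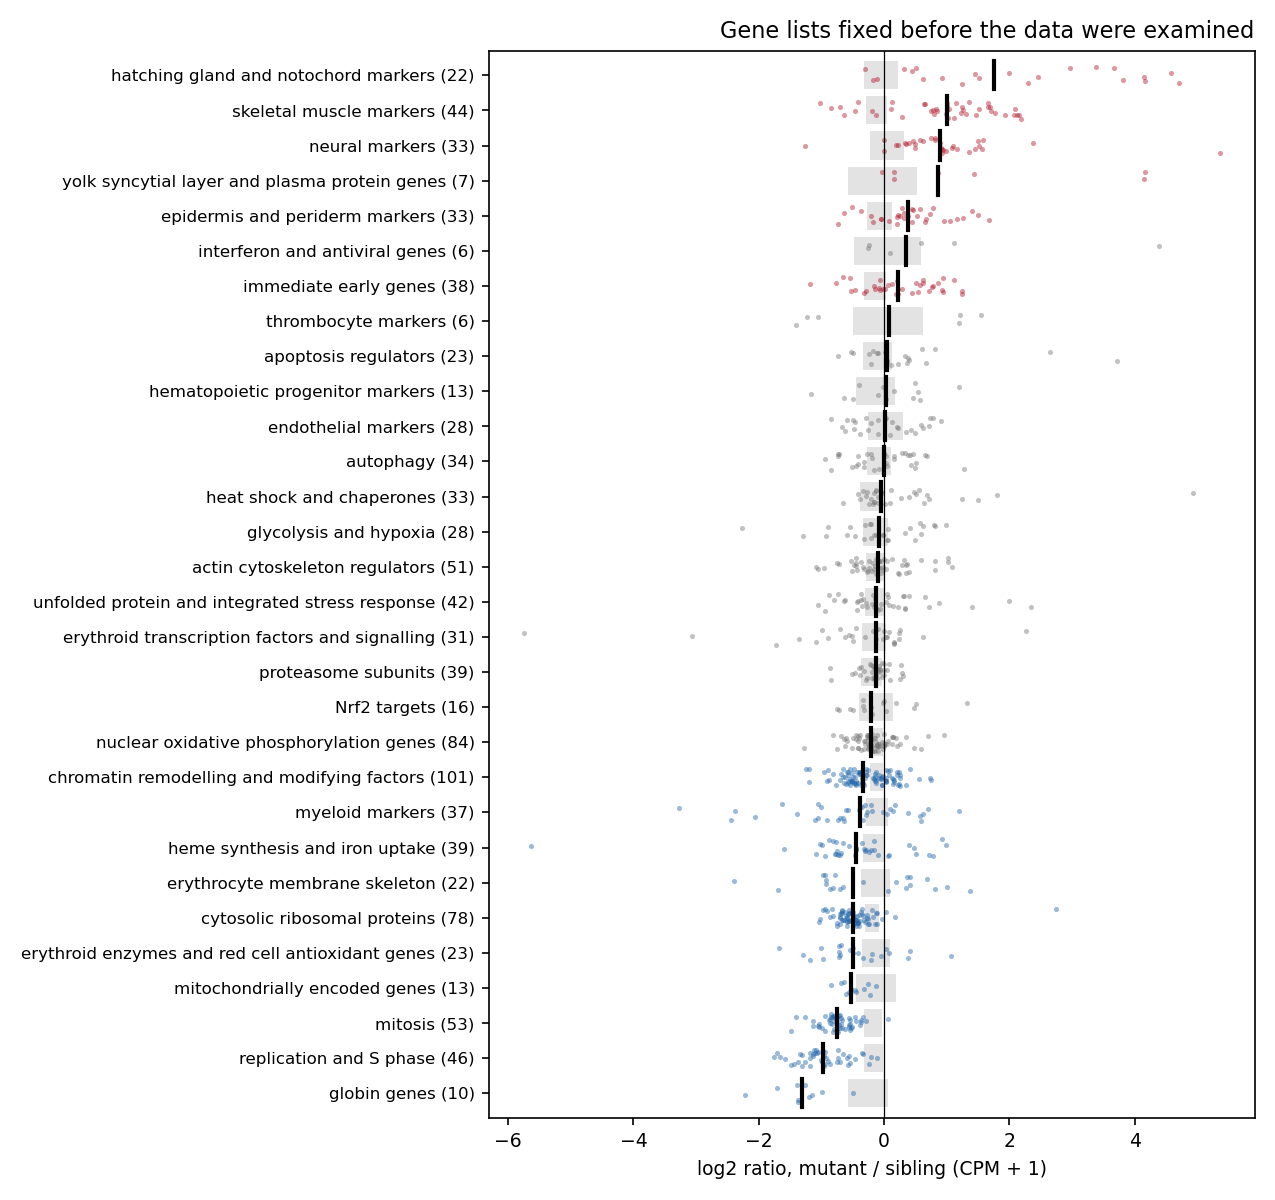
Log2 ratio of mutant to sibling CPM (each + 1) for the measured members of 30 gene lists, 1 point per gene and a black bar at each median, with the number of members in brackets and gray boxes for the central 95% of 10000 random lists. Of the medians, 6 lie above the box (red) and 10 below it (blue).

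Of the 30 lists reported that had at least 5 measured genes, 16 stood apart from random lists, 6 higher and 10 lower. If the genes of a list varied independently, 1.5 would be expected. Genes of a list can vary together, so 16 cannot be judged against that number. The percentiles describe these 2 libraries and are not p-values.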

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

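3 alternatives were chosen after the data were seen. Leaving out the genes at the start of chromosome 21 gave 685 higher and 409 lower genes, and a scaling to the erythroid factor list 849 and 285. Leaving out the muscle, neural, epidermis, yolk and hatching gland marker lists gave 620 and 419. These marker lists had all stood apart as higher, so a larger fall among higher genes was built into that choice. The number of genes at least 2-fold higher (685) and lower (421) depended on the rule: 1799 and 879 with a minimum of 1 CPM or no minimum, 194 and 216 with 50 CPM, 285 and 274 with the minimum in both libraries, 1434 and 1438 at 1.5-fold, 142 and 41 at 4-fold, and 434 and 150 with FPKM. Stricter rules hold fewer genes by construction. With CPM by library total 248 genes were lower, and with a pseudocount of 5, 426 were higher. The *add1* log2 ratio of -5.73 was -4.73 with a pseudocount of 5 and -4.61 with FPKM, which changes both the scaling and the weight of the added constant. The membrane skeleton list reversed, from -0.50 to 0.024 with a minimum of 1 CPM; the cause was not tested, here or for the changes below. With the same minimum the yolk list no longer stood apart (0.18, percentile 70), nor did the myeloid (-0.30, percentile 11.7) and mitochondrially encoded (-0.48, percentile 10.5) lists with 50 CPM. Apoptosis regulators (0.28) and heat shock genes (0.01) stood apart with 50 CPM. No other list median changed its side of the percentiles, but scalings move a list and its random lists alike and could hardly have changed it. Of 959 values of named genes, 202 moved beyond their counting interval and 0 reversed. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Depth limits low genes most: 10 CPM is 57.5 to 63.7 counts, and a gene with 0 counts can lie anywhere up to 0.521 CPM in the sibling library.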

Other observations

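All tests of explanations in this part were chosen after the results were seen, and the genes and clusters described next were picked after their values were seen. A tandem cluster on chromosome 12 (16470534 to 16829977, GRCz10) that holds 2 copies of *ctslb*, a cathepsin L gene of the hatching gland, was higher as a block. All 12 of its measured genes were at least 4-fold higher in the mutant library, and their sum was 18.7-fold higher (18 to 19.3), at 11537 against 618 CPM. Reads shared among the genes of the cluster could not be traced, so they cannot be counted as 12 separate changes.

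The erythroid program differed gene by gene. *klf1*, an erythroid Krüppel-like factor, was at 332 against 853 CPM and *nfe2* at 94.6 against 201 CPM, while *lmo2* (885 against 946 CPM), *gfi1b* (679 against 681 CPM) and *myb* (435 against 388 CPM) were close. Other adducin and skeleton genes went both ways, with 10 of the 22 measured members of that list higher: *add2* was at 188 against 360 CPM, *epb41b* at 790 against 1498 CPM and *sptb* at 1508 against 2383 CPM, but *add3a* at 34.4 against 26.6 CPM and *tpm3* at 758 against 570 CPM. The clone-named *si:ch211-5k11.12*, which lies within the span of *hbbe1.1* on chromosome 3 and stood outside the globin list, was at 6627 against 23250 CPM. The nuclear RNA *malat1* was the most abundant RNA of the mutant library, at 17107 against 13771 CPM.

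The near-absence of RNA from the start of chromosome 21 to the end of *add1* is the pattern most in need of a check at the DNA level. A chance run of low genes is argued against, since 0 of 9304 windows of 10 measured genes outside the region had a median log2 ratio of -2 or less, the lowest being -1.22. A haplotype whose reads map poorly to the reference cannot be told apart from loss of this part of the chromosome in the mutant embryos, since 0 of the 12 measured genes kept more than 25% of the sibling level but the stretch was chosen for its low levels, so that count excludes neither. The 12 genes kept 0.50 to 7.97%, the 7 with at least 900 sibling counts 1.39 to 2.25%, while *zgc:152948* (9 against 102 counts, 12.6-fold lower, 6.36 to 28.2) kept more than that range by more than its counting interval. Silencing of the region stays open too, and the small remainder may come from sibling cells, reads shared with other loci or index exchange, none of which was tested.

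Globin and other erythroid genes could be lower because fewer of the sorted cells were erythroid. The values argue against a gain of all other cell types by a like amount. The skeletal muscle median lay 0.99 above the endothelial one, and the quartiles of these lists did not overlap. A gain of some cell types and not others was not tested. A lower share of erythroid cells alone would lower genes used only by these cells by a like factor. The globin quartiles (-1.39 to -1.16) lay below those of the heme list (-0.77 to -0.13) and the erythroid factor list (-0.66 to 0.12). These values argue against a lower share as the whole cause for these lists, unless other sorted cells use the genes too. That use was not tested, and a lower share stays open as a part of the cause. A less mature state of the erythroid cells is a candidate explanation that these values cannot decide. The globin median lay at -1.34 relative to the hematopoietic progenitor median, and 5 of the 13 progenitor genes are in other lists. The progenitor list did not stand apart (0.03, percentile 86.7), so this gap restates the lower globin level. It cannot tell a less mature state from a lower share of erythroid cells. How the lower S phase and mitosis genes relate to a less mature state was not tested. With 1 library per genotype a difference in embryo age or gating is also open and untested. Loss of the neighbours of *add1* in place of *add1* stays open, because 11 other measured genes, *jak2a* and *fech* among them, were nearly absent in the same library.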
